A study of Mus musculus with 4 samples.

How the data were processed

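Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to recover DNA bound by Foxp1, a forkhead family transcription factor, from basal and from luminal epithelial cells of the mouse mammary gland. The cells came from wild-type females of the FVB/N strain aged 10 to 12 weeks. For each cell type the series holds 1 Foxp1 ChIP library and 1 library of input DNA, that is, chromatin prepared without an antibody. Per the labels' protocols, a commercial ChIP kit was followed by indexed Illumina library preparation, and single reads of 75 to 85 bp were sequenced on a NextSeq instrument. A control antibody was not among the 4 libraries analysed here.

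The values the authors deposited are raw read counts per gene, not normalized. Per the submitters' processing notes, the reads were counted with featureCounts and the genome build was mm10; the aligner, the tool versions, the treatment of duplicate reads and the part of each gene that was counted are not given in the sources used here. The table pairs an Entrez gene ID and a symbol with 4 counts, and the same counts are held in 1 file per sample; 24548 of 24548 genes were equal in each of the 4 files. One gene has the symbol NA and was kept under its ID. Gene positions were taken from a table of NCBI RefSeq genes on assembly GRCm38.p6, the assembly of the mm10 build, in which 24480 of the 24548 gene IDs were found. That table has no strand and no base composition.

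The counted region was examined on the values themselves. On the autosomes, input counts depended little on gene length: the median count summed over the 2 inputs was 293 in the 2339 shortest genes (28 to 949 bp) and 365 in the 2336 longest (100796 to 2270506 bp). Among genes under 1500 bp with neighbours under 1500 bp, the median was 0 in the 41 genes with another gene within 500 bp, 321 in 28 genes at a gap of 4000 to 5000 bp, 365 in 40 genes at 5000 to 6000 bp and 335 in 243 genes beyond 20000 bp. Intermediate gaps held few genes, with a median of 119 in 13 genes at 2000 to 3000 bp and 297 in 14 genes at 3000 to 4000 bp. From these values the counted region was taken to be of similar size for each gene, some kilobases wide, with reads falling in the regions of 2 genes not counted; no source used here states this. Genes close to another gene had fewer reads, and 848 genes were at 0 in all 4 libraries. A value reported for a gene refers to this region, not to a called binding site, and no peak positions were used here.

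Counts were scaled with TMM factors over the 4 libraries (edgeR 4.0.16 in R 4.3.3), computed on the 23128 genes with at least 40 counts over the 4 libraries; the other 1420 genes were not tested. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. With 1 library per group no spread between replicates can be estimated, so no count model was fitted and no p-value is given. Each difference is a log2 ratio of scaled counts with an exact Clopper-Pearson interval of the 2 counts, at 99%. A count of 0.5 was added to both libraries only for the 2 tested genes with a 0 in a library. The ratio of ratios between cell types has an interval from the 4 counts plus 0.5. A gene was called higher or lower at 1.5-fold or more with a 99% interval that excludes 1. These intervals cover counting error only, compare libraries rather than conditions, and treat reads as independent molecules, which PCR copies are not.

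Background was measured in 2 ways. The same rule was applied to the 2 inputs against each other, which hold no antibody signal. The spread among olfactory receptor genes, which are used mainly by sensory neurons, was compared with counting error after the counts had been seen. Gene lists were fixed before the data were examined (17 by name, such as basal, luminal progenitor, mature luminal, fibroblast, endothelial, leukocyte and adipocyte markers, and 6 by symbol pattern). No gene of the mitochondrial genome was in the table, so that list was empty. A list was called when its median log2 ratio lay in the lowest or highest 2.5% of 10000 random lists of the same size. These were matched on mean count over the 4 libraries, ChIP included, in 10 bins. This describes these libraries and is no test across animals. Some lists share members: Klf4 and Klf6 are both FOXO targets and immediate-early genes, and basal markers share 3 genes with the extracellular matrix list.

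Genes named in the text followed a rule fixed before the data were examined: per cell type the 12 genes with the highest lower bound and the 8 with the lowest upper bound, for the difference between cell types 10 at each end, a fixed set of mammary and Foxp genes, and the extreme members of each list; predicted and clone-named genes were left out of the ranking. A few genes outside it are named as examples of a count, chosen after their values were seen, and a few genes that the rule selects are not reported here. Alternatives were total-count scaling, DESeq2 1.42.0 size factors, other count filters, the inputs summed as a shared background, libraries thinned to the smallest total, a reduced gene set, removal of a trend on gene length, and other fold and interval limits. The planned correction for base composition was not run, and length alone was used. A further 3 alternatives were chosen after seeing the data: an interval widened by the olfactory receptor spread, genes with at least 250 input counts, and ratios centred on olfactory receptors.

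The rule was tested on simulated counts for the 23128 genes, with 200 genes changed in basal ChIP. With Poisson counts it recovered 50.0% of genes changed 1.5-fold, 86.0% at 2-fold and 98.0% at 3-fold, and called 52 unchanged genes. With a dispersion of 0.01 added, it recovered 42.0%, 88.0% and 98.0%, and called 582 unchanged genes in basal ChIP over input, 610 in luminal ChIP over input, 563 between the inputs and 1971 by the difference between cell types. The data had 1920 calls in basal ChIP, well above the simulated number, 839 in luminal ChIP, modestly above it, and fewer than simulated between the inputs (271) and by the difference (1868). Spread between libraries beyond counting error therefore adds calls at this rule.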

Results

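Foxp1 ChIP-seq was run on basal and luminal mammary epithelial cells of the mouse, with 1 Foxp1 ChIP library and 1 input library per cell type. Basal cells form the outer, contractile layer of the mammary ducts, and luminal cells line the lumen and give rise to the milk-secreting cells. The gene regions held 3772902 reads in basal ChIP, 3080114 in basal input, 3163948 in luminal ChIP and 4201459 in luminal input. These are reads in counted regions; the total sequenced is not given in the sources used here. The median tested gene had 160 reads in basal ChIP, 144 in basal input, 136 in luminal ChIP and 192 in luminal input. No group had a replicate, so every interval below covers counting error only and no difference was checked against the spread between animals or cultures.

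Which genes were enriched in Foxp1 ChIP in basal cells was addressed by basal ChIP over basal input; without a control antibody this ratio does not separate Foxp1 binding from recovery of DNA that does not depend on the antibody. The Foxp1 gene itself (Entrez gene 108655, protein-coding, chromosome 6, 98925342 to 99522746, GRCm38) was among the highest, with 551 reads in ChIP and 203 in input, a 2.30-fold ratio (99% interval 1.86 to 2.87). Ranked by the lower interval bound, the highest were Zfp36l1, an RNA-binding protein that promotes mRNA decay, at 2.82-fold (2.24 to 3.59), Trib1, a pseudokinase, at log2 1.44, and Pim1, a serine/threonine kinase, at log2 1.39. Sfn, the epithelial 14-3-3 protein sigma, stood at log2 1.32, Hyal1, a hyaluronidase, at 1.40, Ppp6r2, a regulatory subunit of protein phosphatase 6, at 1.42, Capns1, the small calpain subunit, at 1.27 and Chic2 at 1.24. Anp32b and the noncoding RNA Neat1 were also among the 12 highest, at log2 1.27 and 1.25. The ribosomal DNA repeat Rn45s, which is present in many copies, had the most reads of any gene in each library and a log2 ratio of 1.16.

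Immediate-early genes, which are induced within minutes of stimulation, were the list with the highest median in basal ChIP. Of 22 measured, 18 were called higher and none lower, with a median log2 ratio of 0.74 against 0.20 to 0.48 in the central 95% of matched random lists. Junb had a log2 ratio of 1.18, Zfp36 of 1.12 and Egr2 of 0.79, and Myc had 387 reads over 164; Nr4a2 (0.26) and Ier3 (-0.19) did not pass. With the inputs summed as background 13 were still called. The list of FOXO and insulin pathway targets had a median of 0.43 (random lists 0.05 to 0.31), with 10 of 32 called higher and none lower. Its highest members were Trib1 and the pro-apoptotic Bcl2l11 (1.09), the growth factor receptor Igf1r (0.99) was called too, and its lowest were Gadd45a (-0.46) and Tnfsf10 (-0.27), neither of which passed. Of the mammary stem cell and quiescence list, 8 of 23 were called higher and none lower, with a median of 0.41 (random lists 0.01 to 0.33). Besides Foxp1 these included the Notch effector Hes1 (0.98), the cell cycle inhibitor Cdkn1b (0.90), Nfatc1 (0.86) and the tetraspanin gene Tspan8. Tspan8 (Entrez gene 216350, chromosome 10, 115816817 to 115849893) had 319 reads in basal ChIP and 165 in input, 1.64-fold (1.28 to 2.12). Rbl2 (-0.52) and Rbl1 (-0.34), members of the retinoblastoma family, were lowest in that list and did not pass. When both inputs were summed as background, Tspan8 stood at log2 0.54 and was no longer called.

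Basal markers were also enriched in basal ChIP, with a median log2 ratio of 0.47 (random lists -0.05 to 0.23); 6 of 25 were called higher, none lower and 23 lay above 0. The basal keratin genes Krt14 (0.86) and Krt5 (0.79) were highest, Acta2, the smooth muscle actin gene, stood at 0.47 without passing, and Trp63, the basal lineage regulator, did not pass with 212 reads over 180. With the inputs summed, 10 of the 25 were called higher. Wnt pathway genes had a median of 0.30 (random lists -0.05 to 0.20) with 6 of 35 called higher and none lower, led by the transcription factor Tcf7l2 (0.90) and the receptor Fzd7 (0.77). Extracellular matrix genes had a median of 0.18 (random lists -0.11 to 0.15), with 4 of 33 called higher and none lower, among them Hspg2 (0.82) and Lamc1 (0.74). Housekeeping genes had a median of 0.40 (random lists 0.03 to 0.33), with 6 of 24 called higher and none lower, led by Polr2a (1.28) and Eef1a1 (0.90). Ribosomal protein genes had a median of 0.18, and 1 of 38, Rps9, was called higher, none with the interval widened by the receptor spread described below. Luminal progenitor, mature luminal, cell cycle, forkhead, Notch, Hox, histone and zinc finger lists lay within the random range, as did fibroblast, endothelial, leukocyte and adipocyte markers. Fibroblast markers had a median of -0.09, endothelial of -0.21, leukocyte of -0.10 and adipocyte of -0.13, none of them below the olfactory receptor median of -0.21, so that these signs turned with the receptors as centre, and none of their members was called higher. Members of lists within the random range that were called higher included Foxo3 (0.97), Epcam (0.92), Mfge8 (0.77) and Cdk6 (0.71); the call on Epcam was lost with the inputs summed. Olfactory receptors had a median of -0.21, with 1 of 1089 called higher and 89 lower, and the defensin and vomeronasal receptor list had a median of -0.21 over 342 genes, with 2 called higher and 32 lower. With the widened interval the lower calls were 36 and 15, and with the inputs summed 36 and 12, while 6 of the defensin and vomeronasal list were then called higher. In luminal ChIP the lower calls were 30 and 6, with the widened interval 15 and 0, and with the inputs summed 39 and 15.

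In all, 981 of 23128 genes were called higher and 939 lower in basal ChIP. Of these, 128 and 222 were at or past 2-fold. The lowest genes by the upper bound were Mdh1, Aldh6a1, Rasef, Chmp7, Usmg5, Aste1, Aldh5a1 and Ssna1, all with 45 or fewer input reads. Mdh1, a malate dehydrogenase gene, had 0 reads in ChIP and 17 in input, a ratio with an upper 99% bound of 0.31. With a floor of 3 counts set for the ChIP library it would be 6.68-fold lower. Chmp7 had 9 reads in ChIP and 40 in input. Rasef and Aldh5a1 were no longer called with the widened interval. The share of higher among all calls depended on the scaling: with total counts 696 were higher and 1312 lower, and with ratios centred on olfactory receptors, which placed the median of all genes at 0.20 in basal and 0.065 in luminal cells, 2994 were higher and 237 lower. The share of calls that were higher was 51.1% as reported, 34.7% with total counts and 92.7% with the receptors as centre.

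**Figure D1:**
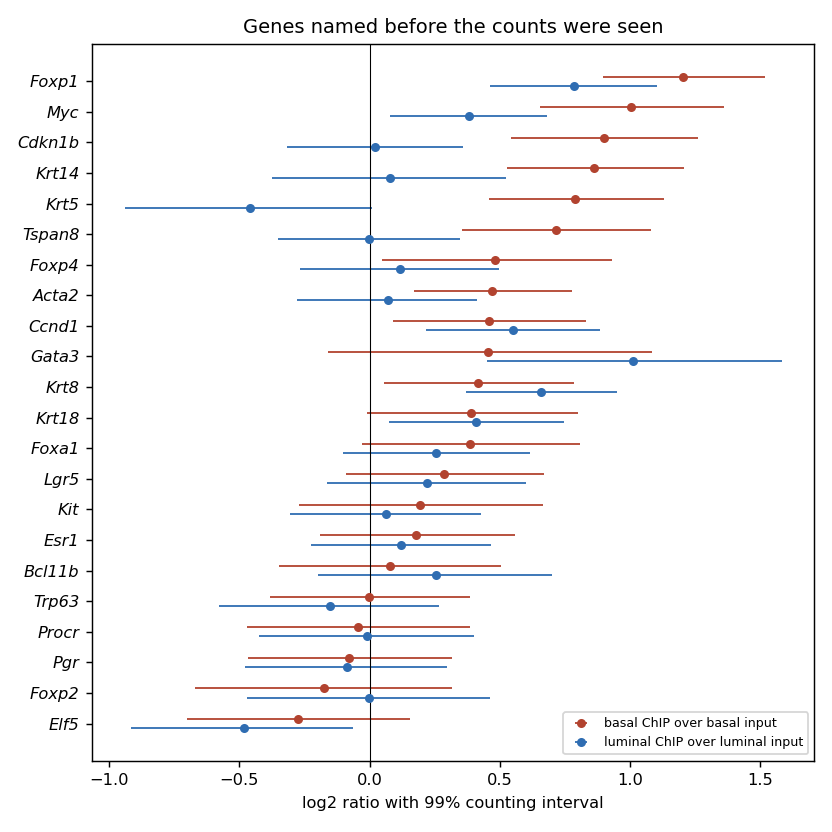
The log2 ratio of ChIP over own input (x axis) is shown for the 22 genes named before the counts were seen (y axis), in basal cells (red) and luminal cells (blue); points are single pairs of libraries and bars are 99% counting intervals. Foxp1 lay above input in both cell types (2.30-fold and 1.72-fold), whereas Krt5, Krt14, Cdkn1b and Tspan8 were called in basal cells and not in luminal cells.

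Luminal ChIP over luminal input gave the same comparison in luminal cells. Ranked in the same way, the highest genes included the microRNA gene Mir3074-2 (log2 1.96), Anp32b, which encodes a histone-binding acidic protein, at 2.57-fold (99% interval 2.12 to 3.14), Neat1 (1.21) and Mir21a (1.16). Mir17 reached 2.32 on 33 ChIP and 9 input reads. The zinc finger factors Klf6 (1.24) and Klf4 (1.06), the transcription factor Mga (1.15), Tardbp, an RNA-binding protein (1.03), Lsmem1 (1.17) and Plet1os (1.11) were also among them, together with Rn45s (0.81). Foxp1 had 315 reads in ChIP and 249 in input, 1.72-fold (1.38 to 2.15). Tspan8 did not pass, with 202 reads over 275 (interval 0.783 to 1.27).

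Immediate-early genes again had the highest list median in luminal ChIP, 0.50 against 0.09 to 0.31 in random lists, with 10 of 22 called higher and none lower. Junb had a log2 ratio of 0.91 and Zfp36 of 0.81, while Ier3 (-0.43) and Nr4a2 (-0.24) were lowest and did not pass. Ribosomal protein genes had a median of 0.19 (random lists -0.10 to 0.13), although their mean was 0.08 and 1 of 38, Rpl27, was called higher at 1.51-fold, a call lost with total counts. No other list was called in luminal cells. Of 23 mature luminal markers 5 were called higher and none lower, with a median of 0.15 just inside the random range of -0.09 to 0.16. Gata3, a regulator of luminal fate, was highest in that list with 114 ChIP and 77 input reads, 2.02-fold (1.37 to 2.99), followed by Epcam (0.76), and the luminal keratin gene Krt8 stood at 1.58-fold (1.29 to 1.93). Esr1 (0.12), Pgr (-0.09) and Foxa1 (0.26), which act in hormone-sensing luminal cells, did not pass, and neither did Elf5 (-0.48) or Kit (0.06) of the luminal progenitor list. Basal markers had a median of -0.01, with 1 of 25, Wnt10a (-0.70), called lower and none higher; that call was lost with the widened interval. FOXO and insulin targets had a median of 0.16 and 4 of 32 called higher, among them Klf4 and Klf6.

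In luminal ChIP 347 genes were called higher and 492 lower, of which 47 and 132 were at or past 2-fold. With total counts the numbers were 268 and 605, and with ratios centred on olfactory receptors 571 and 306, so that the share higher was 41.4% as reported, 30.7% and 65.1%. Fibroblast (-0.03), endothelial (-0.11), leukocyte (-0.12) and adipocyte markers (-0.20) had medians within the random range. Mis12, Ddit3, Cebpz, Trappc4, Setd3, Mdh1, Fancd2 and Rev3l were lowest by the upper bound, with 2 to 13 reads in luminal ChIP and 26 to 77 in luminal input. Mis12 (-2.12 in luminal and -1.03 in basal cells) and Mdh1 were called lower in both cell types, the basal call on Mis12 and the luminal call on Setd3 being lost with the widened interval.

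**Figure D2:**
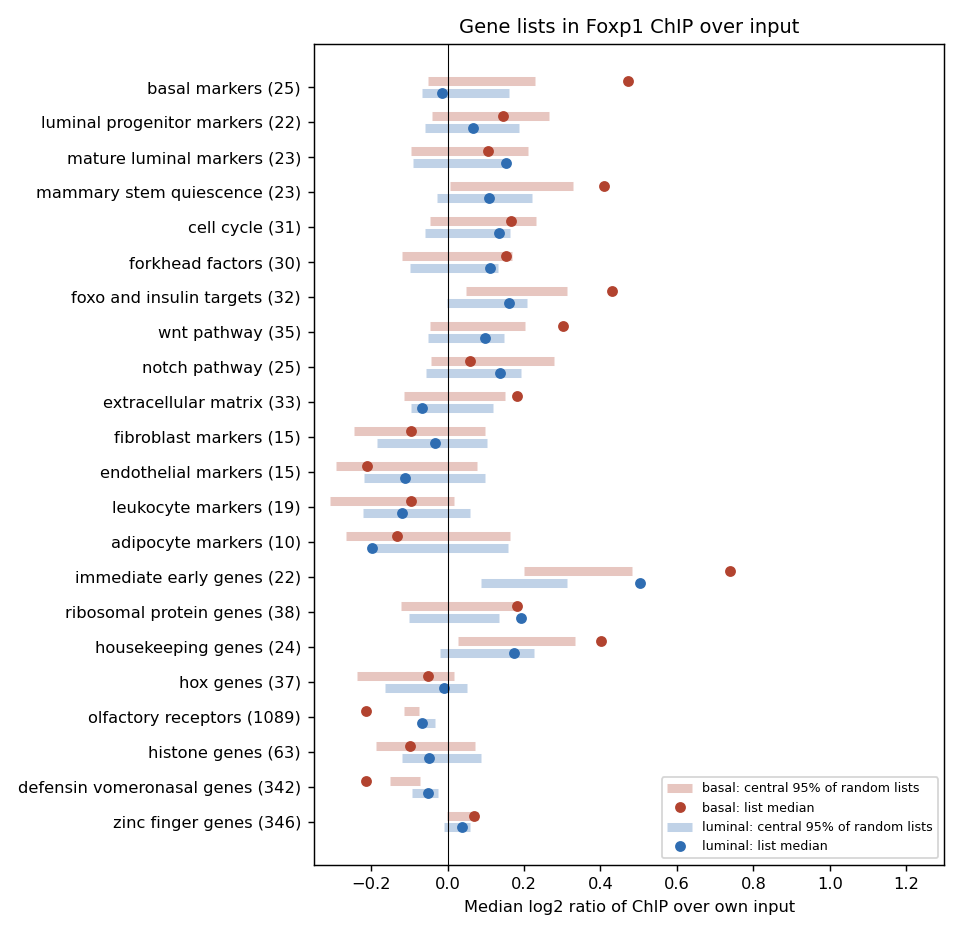
Median log2 ratio of ChIP over own input (x axis) of each gene list (y axis, with the number of genes tested), in basal (red) and luminal cells (blue); bars give the central 95% of 10000 random lists matched on mean count. Immediate-early genes lay above the bars in both cell types (0.74 and 0.50), and basal markers did so in basal cells alone (0.47 against -0.01).

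Background was measured by the 2 inputs against each other. Under the same rule 164 genes were higher in basal input and 107 in luminal input, 271 in all, fewer than in either comparison of ChIP with input. Basal markers were higher in basal input (median log2 0.26, random lists -0.13 to 0.07), and luminal progenitor and mature luminal markers were higher in luminal input (medians -0.20 and -0.24). Between the ChIP libraries compared directly, basal markers had a median of 0.61. Olfactory receptors had a median of 0.21 in basal over luminal input, the opposite sign to their basal ChIP ratio. Basal input is the divisor of that ratio, so the signs are not independent. Between the ChIP libraries directly their median was 0.065. For each pair of libraries, the variance of counts around a common split of each gene's reads was divided by that expected from counting alone. Among olfactory receptors this ratio was 2.29 in basal ChIP over input, 2.13 in luminal ChIP over input and 1.32 between the inputs. Between the ChIP libraries it was 3.08. The receptor spread was thus wider in each comparison with a ChIP library than between the inputs, which alone understate it. Among all tested genes the ratio was 4.46, 2.87 and 1.91 in the same order, and 3.88 between the ChIP libraries. When the interval was widened by the receptor spread, 821 genes were still called higher in basal ChIP and 227 lower, and 259 and 121 in luminal ChIP.

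Whether the same genes were enriched in both cell types was examined next. Of the genes called higher, 108 were shared, where 14.72 would be shared by independent lists of these sizes and 38.89 by lists drawn within bins of mean count; 9 of them were immediate-early genes, among them Fos, Jun, Junb, Atf3 and Ier2, and others were Foxp1, Foxo3, Hes1, Epcam and Eef1a1. Among genes called lower, 29 were shared, where 19.98 would be by independent lists and 33.27 within bins of mean count, so that this sharing was not above the matched number. With the widened interval 4 were shared. Called higher in basal and lower in luminal cells were 2 genes, Phkb and Mir3472, and 8 the other way, among them Uqcrq, Mir99a and Mir133b, where 20.87 and 14.09 would be by independent lists and 7.18 and 8.75 within bins of mean count. The genes called higher in basal cells had a median luminal log2 ratio of 0.25 and 81.9% lay above 0, against 49.6% of all tested genes and 70.3% of genes matched on mean count. The comparison matched on count was added after the values were seen. Its mean count was taken over all 4 libraries, ChIP included, so the bins partly follow the calls themselves. It therefore does not show how much sharing count alone gives. Across genes, which are not independent replicates, Pearson's r between basal and luminal log2 ratios was 0.21 and Spearman's rho was 0.25. Libraries split at random into a pair of equal parts gave r = 0.52 within basal and 0.40 within luminal cells, from which the highest r that counting noise allows between full libraries is 0.62. Among genes with at least 250 input counts r was 0.35, and among olfactory receptors it was -0.04.

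**Figure D3:**
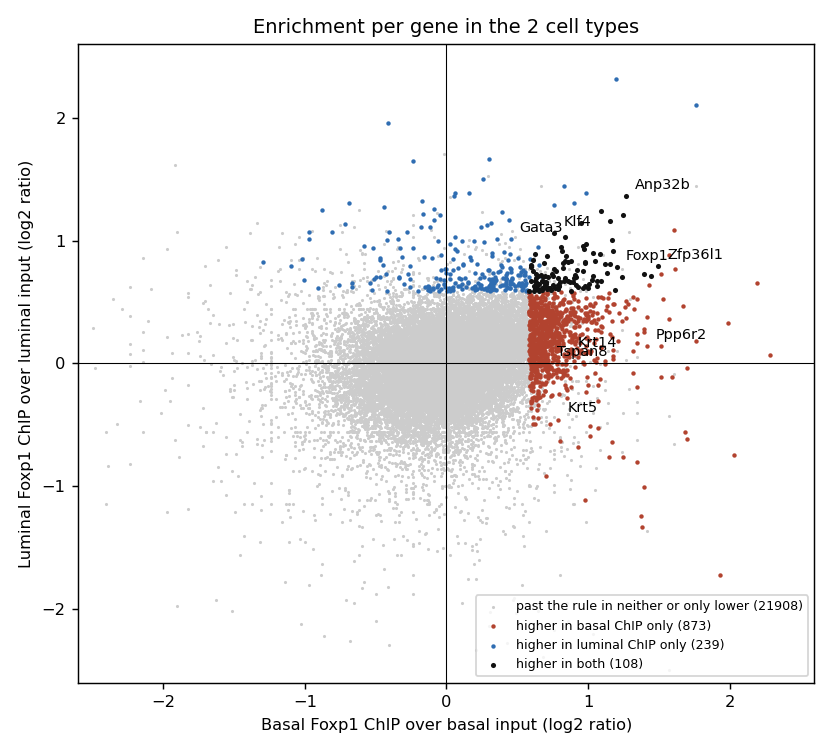
Log2 ratio of basal ChIP over basal input (x axis) against luminal ChIP over luminal input (y axis) for each tested gene; 15 genes lie outside the axes. The 108 genes called higher in both cell types are black, and the 873 and 239 called higher in basal or in luminal cells alone are red and blue.

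The difference in enrichment between basal and luminal cells was taken as a ratio of the 2 ratios. Basal markers differed most among the lists, with a median log2 difference of 0.41 (random lists -0.11 to 0.21), 8 of 25 called higher in basal cells and none in luminal cells. Krt5 differed by 1.25 (standard error 0.22), having 383 reads in basal ChIP over 188 in input and 99 in luminal ChIP over 185. Wnt10a differed by 1.05 and Krt14 by 0.79. FOXO and insulin targets (median 0.30, 3 of 32 higher in basal cells and none in luminal cells), extracellular matrix genes (0.24, 1 of 33, Hspg2) and the stem cell and quiescence list (0.26, 6 of 23 higher and 1 lower) also lay above random lists. Extracellular matrix genes were higher in basal input as well (median 0.11, random lists -0.11 to 0.09). With the widened interval 3 basal markers and 2 of the stem cell and quiescence list were still called. With the inputs summed, 13 basal markers were called higher and 1, Acta1, lower, and 10 extracellular matrix genes and 2 of the stem cell and quiescence list were called higher. With a shared background the inputs cancel, so this difference is the ratio of the ChIP libraries, not corrected for differences between the inputs. In that setting the FOXO and insulin targets (median 0.148, random upper limit 0.151) and the stem cell and quiescence list (0.172, upper limit 0.173) lay just inside the random range. Basal markers and extracellular matrix genes, both higher in basal input, still lay above random lists. Cdkn1b (0.88, standard error 0.19), Igf1r (0.78), Nfatc1 (0.76) and Tspan8 (0.72, standard error 0.19) were called higher in basal cells, and Rbl2 (-0.63) in luminal cells. The Wnt list had a median of 0.12 within the random range, although Fzd2, Fzd7 and Tcf7l2 were among 7 of 35 called; 3 were called higher with the widened interval, and 3 higher and 1 lower with the inputs summed. Foxp1 differed by 0.42 and was not called. Mature luminal markers had a median difference of -0.12, within the random range of -0.14 to 0.21, with Prlr called higher in luminal cells and Wnt5a in basal cells. With the inputs summed their median was -0.343, below random lists, with 4 called higher in luminal cells and none in basal cells. Luminal progenitor markers had a median difference of 0.17, which turned to -0.179, below random lists, with the inputs summed. The difference calls on Rbl2, Tcf7l2 and Wnt5a were lost both with the widened interval and with the inputs summed, that on Prlr with the widened interval and that on Fzd7 with the inputs summed. Fibroblast markers lay just below random lists (-0.25), and with the inputs summed their median was 0.142. Olfactory receptors differed by -0.15 and the defensin and vomeronasal list by -0.17, and these too turned positive with the inputs summed (0.065 and 0.081). Of the 1089 receptors, 13 were called higher in basal and 106 in luminal cells by the difference, and 3 and 20 with the widened interval.

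Of all genes, 893 were called higher in basal and 975 in luminal cells. Simulated libraries gave 162 such calls among unchanged genes with Poisson counts and 1971 with a dispersion of 0.01, the latter more than these together. That dispersion was set, not estimated from the data, and gave 563 calls between the inputs where the data had 271. The simulated number thus depends on the dispersion, and the number of calls alone does not show differences between the cell types. With ratios centred on olfactory receptors 2088 were higher in basal and 420 in luminal cells. The receptors were themselves higher in basal input (median 0.21), and this centring carries that difference into the ratios. Which side had more was not stable: it also reversed with DESeq2 size factors (939 and 932), thinned libraries (894 and 871), the length trend removed (994 and 851), a 1.2-fold limit (1181 and 1062) and the interval widened. With the interval widened by the receptor spread these were 210 and 130, and the calls on Krt14 and Tspan8 were lost while those on Krt5 and Cdkn1b were kept; with the inputs summed, Krt5 and Krt14 were kept and Cdkn1b and Tspan8 were lost. The extreme genes by the interval bound had fewer reads in each library than the median tested gene, except Mir3074-2 with 160 in luminal ChIP. Several of these calls were lost with the widened interval (among them Samd4b, Mir574, Gpc2, Wdr46 and Mrpl40). On the basal side they were Ddit3, Tmem179b, Slc26a11, Rev3l, Fancd2, Lrrc8a, Padi3, Gpc2, Samd4b and Mir574, with log2 differences of 2.40 to 4.07. Slc26a11, an anion transporter gene, had 53 reads in basal ChIP over 11 in input and 14 over 32 in luminal cells. On the luminal side they included Mir3074-2, Uqcrq, Mir133b, Mir99a, Dner, Vti1a, Mrpl40, Cnpy4 and Wdr46, with differences of -1.69 to -4.79. Uqcrq, a subunit of respiratory complex III, had 34 reads over 53 in basal and 91 over 52 in luminal cells.

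**Figure D4:**
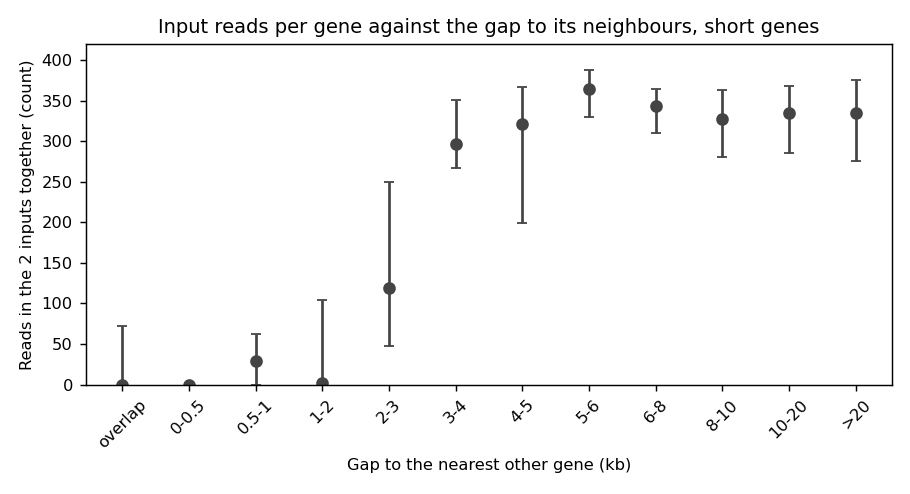
Reads per gene in the 2 inputs together (y axis, counts; points are medians, bars the interquartile range) against the gap to the nearest other gene (x axis, kb) for autosomal genes under 1500 bp with short neighbours. The median was 0 below 500 bp, 321 at 4000 to 5000 bp and 335 beyond 20000 bp.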

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

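The tests in this part were chosen after the results were seen. Among the named genes, 4 lay above input in one cell type and below it in the other with both 99% counting intervals excluding 0; with 1 library per group none of these differences was tested across animals. Uqcrq had a log2 ratio of -0.88 in basal and 1.25 in luminal cells, a difference of -2.13. Mir133b differed by -1.69 and Mir99a by -2.13, both lower than input in basal and higher in luminal cells. With the interval widened by the receptor spread the basal call on Uqcrq, the luminal call on Mir133b and both calls on Mir99a were lost, and with the inputs summed the basal call on Uqcrq and the luminal calls on Mir133b and Mir99a. Fzd2, a Wnt receptor, stood at 0.61 in basal and -0.44 in luminal cells, a difference of 1.05; its basal call was lost with total counts and with the inputs summed. Of 23128 genes, 27 were beyond their intervals upward in basal and downward in luminal cells, and 24 the other way.

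Immediate-early genes were above input in both cell types, 19 of 22 members in each at once, a count that does not decide alone because random lists matched on mean count had 12 to 19. Counting error does not account for the medians. Their lower 95% counting bounds exceeded the upper limit of such lists by 0.112 or more in both cell types. These bounds cover counting error only. The lists were matched on mean count in 10 bins, ChIP included, so a count-related effect of the libraries within a bin was not excluded. The difference between the inputs is argued against too, since with the inputs summed the lower of the list medians, that of luminal cells, was 0.583, above the random upper limit of 0.348. A preference of immunoprecipitated DNA for active promoters whatever the antibody stays open: housekeeping and ribosomal protein genes lay above random lists in 3 of 4 cases. FOXO and insulin targets did not stand apart from housekeeping genes, by 0.027 in basal cells (label permutation range -0.246 to 0.277) and -0.011 in luminal cells (-0.185 to 0.175). That list was not drawn up as Foxp1 targets, and it shares Klf4 and Klf6 with the immediate-early genes, so it does not decide on Foxp1 binding. For lack of a control antibody, Foxp1 binding and such a preference cannot be told apart here.

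Basal markers were more enriched in basal than in luminal cells (median difference 0.41). The ChIP libraries compared directly gave a median of 0.607. That ratio also holds the difference between the inputs, so it does not test whether the inputs account for the 0.41. The inputs alone showed a median of 0.260 in the same direction, although olfactory receptors, which are no basal markers, stood at 0.21 there. Each ratio is taken over its own input, so this input difference is already divided out and cannot by itself give the 0.41. Whether the ChIP libraries recovered accessible DNA beyond their inputs was not measured, for lack of a control antibody, and remains open. A difference between the cell types in Foxp1 binding is the biological explanation that the design allows, and it was not tested apart from accessibility.

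More genes were called higher in basal than in luminal ChIP, 981 against 347, a ratio of 2.83. Thinning all libraries to one total left the ratio at 2.49, which argues against depth as the whole cause. Intervals widened by the receptor spread left it at 3.17. That spread was nearly the same in both pairs (2.29 in basal and 2.13 in luminal ChIP over input), so widening could change the ratio little. Among all tested genes the spread was 4.46 and 2.87, and with 1 library each library noise remains open. With the inputs summed it was 1.77, so part of it moved with the inputs. It also depended on the limit and the centring, at 1.74 with a 1.2-fold limit and 5.24 with ratios centred on olfactory receptors. The receptors were higher in basal input (median 0.21), which that centring carries into the ratios. How well each immunoprecipitation worked remains open, as does the cell type itself, with 1 library of each.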

How the results depend on the processing

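The widened interval, the 250 input count limit and the centring on olfactory receptors were chosen after the data were seen. No count of called genes over all genes moved by more than 1.5 times under total counts, DESeq2 size factors, no count filter, at least 200 counts, summed inputs, thinned libraries, the gene set without predicted, clone-named and multi-copy genes, or removal of the length trend. No named gene that was called reversed its sign there, although some ratios near input did. Similar counts did not mean the same genes. With the inputs summed, 725 genes were called higher in basal and 410 in luminal ChIP. These held 570 of the 981 higher calls reported for basal ChIP and 263 of the 347 for luminal ChIP. Counts within lists moved more with the inputs summed: basal markers called in basal ChIP went from 6 to 10, and by the difference basal markers went from 8 to 13, extracellular matrix genes from 1 to 10, the stem cell and quiescence list from 6 to 2, and Wnt genes from 7 to 3. Lower calls in basal ChIP went from 89 to 36 among olfactory receptors, also with the widened interval, and from 32 to 12 in the defensin and vomeronasal list (15 with the widened interval). The planned correction for base composition was not run, and samples could not be paired by replicate number, since each group has 1 library. A fit of ChIP against input over both cell types, with cell type as block, was possible with 1 residual degree of freedom and was not run. At 2-fold, 128 genes were higher and 222 lower in basal ChIP, 47 and 132 in luminal ChIP, 146 and 252 in basal and luminal cells by the difference, 37 between the inputs, and 5 were shared. At 1.2-fold, 2707 and 1737 were called in basal and 1557 and 1004 in luminal ChIP, 1275 between the inputs, and 716 were shared. A 95% interval gave 452 between the inputs. The widened interval left 227 lower calls in basal and 121 in luminal ChIP, and 210 and 130 by the difference. Genes with at least 250 input counts gave 325 lower calls in luminal ChIP and 154 between the inputs; here fewer genes were tested. Centring on olfactory receptors gave 2994 and 237 in basal, 571 and 306 in luminal ChIP, 2088 and 420 by the difference, and 263 shared.

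The correlation across genes (0.21) was 0.164 with no filter, 0.3125 at 200 counts, 0.3472 at 250 input counts and 0.3042 with the inputs summed. Unchanged libraries simulated against the shared inputs with counting noise alone gave 0.3106. The spread among all tested genes was wider than counting noise (4.46 times in basal and 2.87 times in luminal ChIP over input). The simulation therefore does not show how much of the 0.3042 the shared inputs alone give, and part of it may come from them. With the inputs summed, the median difference turned to 0.142 in fibroblast markers, 0.065 in olfactory receptors and 0.081 in the defensin and vomeronasal list, and it turned negative in luminal progenitor markers (-0.179), adipocyte markers (-0.191) and Hox genes (-0.110). It moved to -0.343 in mature luminal markers and to 0.148 in FOXO and insulin targets. The defensin and vomeronasal list's basal median was 0.000 when centred on olfactory receptors. With the inputs summed, the median differences are those between the ChIP libraries directly, because a shared background cancels. The cause of the changes in the other settings was not tested. Few reads per gene limit what can be called, most of all at 1.5-fold.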

Other observations

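The tests on Klf genes and on keratins were fixed after lists of the extreme genes had been seen but before the medians they measure, and those on the inputs and on partly counted regions after their values. Klf4, Klf6 and Klf9 stood among the highest luminal genes in those lists, which led to the hypothesis that other members of this family of zinc finger factors are enriched too. The 13 Klf genes other than Klf2, Klf4, Klf6 and Klf9 (no reason for leaving these out was recorded) had a median log2 ratio of 0.507 in basal ChIP (random lists -0.061 to 0.364) and of 0.261 in luminal ChIP (random lists -0.072 to 0.245). In basal cells 5 were called higher, Klf5, Klf10, Klf11, Klf13 and Klf16, and 1, Klf12, lower. In luminal cells Klf10 alone was called higher and none lower. A check without Klf10 was added after the values were seen. The other 12 had a median of 0.377 in basal ChIP (random lists -0.079 to 0.339). In luminal ChIP their median was 0.176, inside the random range of -0.089 to 0.233. Leaving out any other gene above the median of the 13 gives the same medians, so this is not particular to Klf10. The luminal result was thus lost when such a member was left out, and the basal one stayed just above. Keratin genes gave a negative result: the 47 outside the marker lists, of which Krt13 and Krt87 had been seen among the extreme genes, had a median basal minus luminal difference of -0.049, inside the random range of -0.163 to 0.093, with 5 called higher in each cell type, so the difference of Krt5 and Krt14 was not shared by the family at large.

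The input libraries differed at marker genes of the cell types they came from, and at other lists. Basal markers were higher in basal input (0.26) and both luminal lists higher in luminal input (-0.20 and -0.24), as were Hox genes (median -0.13), while extracellular matrix genes were higher in basal input (0.11). Olfactory receptors (0.21) and the defensin and vomeronasal list (0.23) were also higher in basal input, nearly as much as basal markers. Of the 4 non-epithelial lists (fibroblast, endothelial, leukocyte and adipocyte markers), 0 lay outside the random range. Immediate-early genes (median -0.17) and housekeeping genes (-0.09) were lower in basal input but within the random range. Whether the differences follow the cell types therefore remains open. Open chromatin carried over in sheared input DNA could account for the markers, and neither its share nor its bearing on the receptors was tested.

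Regions with few reads held more than their share of the genes called lower than input, but not most of them, and in luminal ChIP of the genes called higher as well. Of those called lower in basal ChIP, 38.1% had under 250 summed input counts, against 23.1% of all tested genes and 14.0% of genes called higher; 581 of the 939 had 250 or more. In luminal ChIP the shares were 39.0% of genes called lower and 28.0% of genes called higher, both above that of all genes. Widening the interval by the olfactory receptor spread kept 821 of 981 higher calls and left 227 lower calls where there had been 939.

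MicroRNA genes had medians of -0.13 in basal and -0.06 in luminal cells over 884 genes, above the olfactory receptor medians of -0.21 and -0.07, so the sign depends on the centring; 20 were called higher in basal and 13 in luminal cells, Mir21a among them in both.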
